A study of Homo sapiens with 4 samples.

How the data were processed

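Total RNA was measured in PC3 and PC3M (PC-3M-luc-C6) cells that had been transfected, per the labels' protocols, with a miR-26a mimic or a negative control miRNA at 10 nM using DharmaFECT reagent. Per the same protocols, the medium was changed after 24 hours and RNA was taken after a further 48 hours. From each sample 100 ng of RNA was labelled with Cy3, per the labels, and hybridized to a 1-colour Agilent SurePrint G3 Human array. The labels give 1 array for each line and treatment, 4 in all, and the file headers show 1 slide and 1 scan, so no slide or scan batch could be separated.

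Spot intensity was deposited for each array as the authors' scanner export, made per the file headers with Agilent Feature Extraction 11.5.1.1, which subtracts background and removes spatial trends within an array and leaves the values on a linear scale with no scaling between arrays. The same files hold the mean pixel intensity of each spot and the median intensity of its local background, per the file headers without correction. The authors also deposited a table of log2 values for which no processing note states the software. For each of 58190 probes it equals the log2 of the processed intensity minus 1 constant per array (100% of probes within 0.01), with the 75th percentile of each array at 0 and no centring per gene. Its column medians were -4.03, -3.88, -3.95 and -3.82. How cultures were replicated before RNA extraction is not given in the sources used here.

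The main values were computed from the scanner files. Control probes were dropped, spots with an outlier mark of the scanner software were removed, replicate spots of a probe were averaged, and log2 of the processed signal minus the array's 75th percentile over non-control probes was taken. Of 58201 probes, 11 had no spot left on some array and were dropped, which leaves 58190. No spot was saturated. The reference gave gene symbols for RefSeq accessions. Of the probes, 31100 were named through their accession, 3365 through a current symbol and 496 through an older symbol, and 23229 kept the name in the file. Probe coordinates are those of the array files, on hg19. A probe was kept when it was well above background, by the scanner software's own mark, on at least 2 arrays. The brightest probe stood for a gene, which gave 24178 genes, 7850 of them with placeholder names. Of the 5679 genes with several probes, 1791 had probes that disagreed in sign.

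miR-26a was compared with control, and PC3M with PC3, in 1 model with terms for cell line and treatment (limma 3.58.1 in R 4.3.3, lmFit and eBayes). The model has 1 residual degree of freedom, moderated with 2.62 prior degrees of freedom and a prior SD of 0.203, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The error term is the disagreement of the 2 lines, so a response of 1 line counts as error. P-values measure only the spread between these samples, which may be technical. Within each line, log2 differences, both levels and counts of genes past 2-fold are given without a test, and a gene not well above background on either array of a line was left out of the counts. The lines' differences were correlated across genes.

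The gene lists, 24 in number, were fixed before the data were examined, as were the comparisons, tests, thresholds, the rule for named genes and the alternatives, except where stated. The lists hold the title genes, reported miR-26a targets, the miR-26 host genes, microRNA machinery, vesicle secretion, prefoldin and CCT, HSP90 and heat shock, SHC and RAS, G1/S, G2/M, p53 targets, interferon-stimulated genes, NF-kB cytokines and cholesterol synthesis. They also hold the stress response, hypoxia and glycolysis, ribosomal proteins, and epithelial, mesenchymal, stromal, leukocyte, endothelial, androgen and luminal, and neuroendocrine genes. For each of the 21 lists with at least 5 tested genes, camera was run with a preset correlation of 0.01 and again with an estimated correlation, and the median per line was placed among 10000 random lists matched on mean expression in 20 bins, as a description only. The other 3 lists are reported by member. A list's median includes all its tested genes unless stated, while counts of lower and higher genes leave out those not well above background on either array of a line. With 1 residual degree of freedom the estimated correlation rests on the sign of 1 residual per gene and the p-value on 1 degree of freedom, so this alternative had little power to call any list. ATP6V0A2, DDX58, IL8, CYR61, CTGF, CD68, LYZ, HBA1 and ACPP had no probe under these names.

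Genes were named by this rule: the 3 title genes, the 10 largest decreases and 10 largest increases by the smaller of the lines' changes, up to 4 members per list with the largest mean difference, the 3 largest changes in each direction per line, the 5 genes furthest apart between the lines among those past 2-fold in opposite directions, and the 8 largest differences in each direction between the lines. Placeholder names and long non-coding RNA accessions were passed over, and not every gene the rule picks is printed. EZH2 was named after its values were seen.

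A planned comparison by miR-26a seed sites in 3' UTRs could not be run, because no UTR or transcript sequence was given. In its place, chosen after the files were seen, the 60-base probe sequences of 14442 mRNA genes were searched. Words of 7 bases found in at least 20 genes, 13115 in all, were ranked by the mean difference of genes with the word against genes without it, after removal of linear trends on GC content and number of probes, both as such and divided by its standard error.

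Each computation was tested on simulated data. For the treatment comparison over 24178 genes, limma recovered 0 of 100 genes at each simulated log2 change of 1, 2, 4 and 6, with median fits of 1.01, 2.01, 4.00 and 6.00 and 0 false calls. Under this simulation the test could not call changes in so few genes. The simulated noise took each gene's SD as fitted with 1 residual degree of freedom, which scatters widely, so power in the data may differ. camera called a list moved by simulation at an adjusted p of 5.2e-32 and 0 other lists. The noise was drawn independently for each gene, so genes that move together were not simulated. For PC3M against PC3 with 30% of the 24178 genes changed, 58.9%, 80.5% and 93.0% were recovered at log2 changes of 1, 2 and 4, with 3.69% false among the calls. The list percentiles placed 4 of 4 lists shifted by 0.5 outside percentiles 1 to 99 and 5 of 5 unshifted lists inside. The word search placed 5 of 5 planted words, each moved by -0.3, in the lowest 1%, and 3 of them ranked first. An earlier, stricter demand that every planted word rank among the top 3 was not met and was replaced by the 1% bound that the written prediction used.

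The alternatives tried were quantile normalization, normexp background correction (offset 50) on mean and local background intensity, the authors' log2 table, probes well above background on all 4 arrays, no filter on dim probes, the mean of a gene's probes, a trended and robust variance prior, no block for the other factor, a 1.5-fold threshold and the estimated correlation. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.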

Results

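Gene expression was measured in 2 human prostate cancer cell lines, PC3 and PC3M (a luciferase-carrying, metastatic derivative of PC3), after transfection with a mimic of the microRNA miR-26a or with a negative control microRNA. Each line and treatment had 1 single-colour microarray, which gave 4 arrays in 4 groups of 1: PC3M control, PC3M miR-26a, PC3 control and PC3 miR-26a. There was therefore no replicate within a line and treatment, and the number of arrays limits the precision of every value. Of the 58196 to 58200 probes with a spot left on an array, 30016 were well above background on the PC3M control array, 30588 on the PC3M miR-26a array, 30260 on the PC3 control array and 30839 on the PC3 miR-26a array. The 10 replicate spots of a probe within an array had a median SD between 0.0548 and 0.0625 on the log2 scale. After filtering, 24178 genes were tested, of which 20638 were well above background on all 4 arrays. Levels are log2 signals relative to the 75th percentile of each array, so that a level of 0 is the level of a gene at that percentile. The arrays measure mRNAs and long non-coding RNAs, so the mimic itself was not measured.

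The series title names PFDN4, CHORDC1 and SHC4 as the genes through which miR-26a regulates secretion of extracellular vesicles, and the question was how these 3 transcripts responded to the mimic. All 3 were lower with miR-26a than with the control microRNA in both lines, by more than 2-fold in each. With normexp background correction all 3 were again lower in both lines, but only 2 of them passed 2-fold in PC3. PFDN4 encodes a subunit of prefoldin, which hands unfolded actin and tubulin to the chaperonin CCT. CHORDC1 encodes a co-chaperone that binds HSP90, and SHC4 encodes an adaptor that couples receptor tyrosine kinases to RAS signalling.

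For PFDN4 (probe on chromosome 20, start 52831885, end 52831944, hg19), the level was 4.11 in the PC3M control and 2.89 after miR-26a in PC3M, and 4.29 and 2.95 in PC3. The mean difference over the lines was -1.28 ± 0.18, which is 2.43-fold lower. Here and below, ± gives limma's moderated SE, which is drawn toward a prior over all genes and is not the spread of the 2 lines alone. For CHORDC1 (chromosome 11, start 89935045, end 89935104, hg19), the levels were 3.73 and 2.25 in PC3M and 2.90 and 1.55 in PC3, with a mean difference of -1.42 ± 0.18, or 2.68-fold lower. For SHC4 (chromosome 15, start 49116147, end 49116206, hg19), the levels were 1.79 and 0.41 in PC3M and 0.64 and -0.46 in PC3, with a mean difference of -1.24 ± 0.19, or 2.36-fold lower. Which part of each transcript the probe lies in is not given in the sources used here. None of the 3 passed the limma test over all genes, with an adjusted p of 0.234 for each. With p-values adjusted over the list alone, 3 of the 3 genes were called lower, but the study chose this list on these samples, so that count is not independent evidence.

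**Figure D1:**
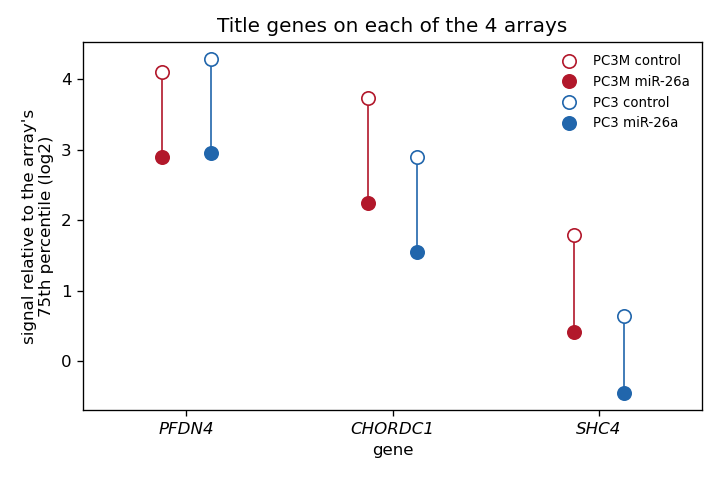
Levels of PFDN4, CHORDC1 and SHC4 (vertical axis, log2 signal relative to the array's 75th percentile) on each of the 4 arrays, with open circles for control and filled circles for miR-26a arrays, PC3M in red and PC3 in blue, joined within a line. Each gene was lower on the miR-26a array of both lines, for PFDN4 from 4.11 to 2.89 in PC3M and from 4.29 to 2.95 in PC3.

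The comparison of miR-26a with control over both lines asked which transcripts responded alike in the 2 lines. Large decreases shared by both lines were in POLR3G, a subunit of RNA polymerase III, in PPIL6, of the cyclophilin family, in EIF2S1, the alpha subunit of the initiation factor eIF2, and in STRADB, a pseudokinase that activates the tumour suppressor kinase LKB1. LOXL2, a secreted enzyme that cross-links collagen, the death-domain adaptor CRADD and the ion-transport kinase STK39 were also lower in both. The largest shared increases were in DHRS2, a mitochondrial dehydrogenase, in LCP1 and ACTG2, an actin-bundling protein and a smooth muscle actin, and in several genes normally restricted to testis or stroma, among them VCX2, XAGE2 and FAP.

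limma called 0 genes lower and 0 genes higher at an adjusted p of 0.05 with 1 residual degree of freedom. The lowest adjusted p was 0.198, reached among the named genes by DHRS2, LCP1, FAP, FRG2, POLR3G and PPIL6, and 3980 genes (16.5% of those tested) had an unadjusted p under 0.05, of which 1967 were lower and 2013 higher. A single gene, DHRS2, was called in alternative settings of limma, where it was higher at an adjusted p of 0.0275 when only probes well above background on all 4 arrays were kept and at 0.0125 with a trended, robust variance prior. The median difference over all genes was -0.05.

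STRADB was 7.33-fold lower in PC3M and 5.25-fold lower in PC3, with a mean log2 difference of -2.63 ± 0.21 (moderated SE). POLR3G had a mean difference of -2.48 ± 0.17, EIF2S1 of -2.28 ± 0.17 and CRADD of -2.11 ± 0.21. A second, dimmer probe gave smaller mean differences for STRADB (-1.91) and POLR3G (-1.30). The mean differences of STK39, OAF, LOXL2 and CREBL2 lay between -2.04 and -1.91, OAF being a secreted protein and CREBL2 a transcription factor related to CREB. PPIL6 was 5.37-fold lower in PC3M and at least 5.44-fold lower in PC3, while its second probe had a mean log2 difference of -1.64. KIF9, a kinesin, was at least 4.31-fold lower in PC3M and 3.88-fold lower in PC3. A bound of this kind sets the brighter array against the higher of 2 signals, the lowest signal among probes well above background on the dim array and the dim probe's own signal.

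DHRS2 went from -0.20 to 6.31 in PC3M and from -1.16 to 4.80 in PC3, a mean difference of 6.23 ± 0.22, or 75.3-fold. LCP1 was 23.3-fold higher in PC3M and 13.4-fold higher in PC3, and ACTG2 was 55.0-fold and 12.9-fold higher. VCX2, a cancer-testis gene on chromosome X, was 266-fold higher in PC3M and 24.3-fold higher in PC3. Its second probe had a mean log2 difference of 3.38, against 6.33 for this one. FAP, a surface protease of activated fibroblasts, was 12.3-fold higher in PC3M and at least 9.27-fold higher in PC3. The receptor tyrosine kinase ROS1 was at least 9.93-fold and at least 8.50-fold higher in PC3M and PC3. XAGE2, another cancer-testis gene, was at least 8.45-fold and 6.65-fold higher. GARIN1B was at least 7.47-fold and 22.5-fold higher, BTBD17 12.2-fold and at least 8.39-fold higher, and FRG2 at least 5.72-fold and at least 10.6-fold higher.

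Transcripts reported elsewhere as miR-26a targets were lower as a group. Of 30 such genes measurable in both lines, 20 were lower in both and 7 higher in both, and the 31 tested had median differences of -0.33 in PC3M and -0.43 in PC3. Among random lists matched on mean expression, these medians fell at percentiles 0.14 and 0.07. The random lists drew genes independently, and several lists with other themes lay about as far out. The stress-response list stood at 99.95 in PC3M and the mesenchymal list at 99.99 in PC3, while the vesicle list stood at 21.4 and 5.48. The percentiles alone thus do not set the reported targets apart. STRADB, LOXL2 and the cell-cycle kinase CDK6 had the largest differences, and CDK6 was 2.58-fold lower in PC3M and 2.71-fold lower in PC3. The growth factor HGF was dim on both control arrays and at least 1.24-fold and at least 1.23-fold higher. IL6, also on the list, was 4.99-fold higher in PC3 and not well above background in PC3M. In PC3 it was the only member more than 2-fold higher, against 7 more than 2-fold lower. The histone methyltransferase EZH2, a much-studied target named here after its values were seen, differed by -0.11 in PC3M and -0.43 in PC3. camera called the list lower (adjusted p = 0.0029), a call lost with an estimated correlation (adjusted p = 0.728). Adjusted over the list alone, 12 of its genes were called lower and 1 higher, against 0 over all genes tested.

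In the list of prefoldin and CCT subunits, 10 of 17 genes were lower in both lines and 2 higher, with medians of -0.18 and -0.31 in PC3M and PC3 (-0.02 and -0.10 with quantile normalization). PFDN6 and VBP1, other prefoldin subunits, differed by -0.82 and -0.51 on average, and the chaperonin subunit CCT6A by -0.46. The list also holds the title gene PFDN4 (-1.28), which the study chose on these samples. A lower list is thus not independent of that choice, and camera was not run without PFDN4. camera called this list lower at an adjusted p of 0.049 (0.808 with an estimated correlation), and the call was absent with quantile normalization (0.531), with all 4 arrays required to be well above background (0.0725) and with the mean of a gene's probes (0.0548). Of 47 measurable genes of vesicle biogenesis and secretion, 29 were lower in both lines and 8 higher, with medians of -0.15 and -0.23 (-0.07 and -0.14 with quantile normalization, where 28 were lower and 19 higher in PC3M). camera did not call the list (adjusted p = 0.0628), but called it lower with normexp background correction (0.0236), with no filter on dim probes (0.0057) and with the mean of a gene's probes (0.0491). The vesicle marker CD9 and the phospholipase PLD1 were lower by mean differences of -0.92 and -1.47, while the sphingomyelinase SMPD3 and the tetraspanin CD82 were higher by 1.61 and 1.01. Adjusted over the list alone, 1 prefoldin gene, PFDN4, and 0 vesicle genes were called lower.

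In the HSP90 and heat-shock list, HSPA1A and HSPA1B, the inducible HSP70 genes, were higher by mean differences of 0.85 and 0.74 and the constitutive HSPA8 was lower by a mean difference of -0.55. The list's median was 0.04 in PC3M and -0.12 in PC3. These medians were 0.16 and 0.10 with quantile normalization and 0.02 and -0.01 with normexp background correction. Over both lines the list's median was -0.07 and its mean -0.01 while camera's direction was up (adjusted p = 0.847). In the SHC and RAS list the medians were -0.08 and 0.07 (adjusted p = 0.766), the latter 0.17 with quantile normalization and 0.02 with normexp background correction, and the ERK phosphatases DUSP4 and DUSP5 and the ERK-induced factor ETV4 had mean differences of -0.71, -1.03 and -0.68. Adjusted over the list alone, CHORDC1 was the 1 gene called lower in the HSP90 list, and 0 genes were called in the SHC list. CHORDC1, like SHC4 in the SHC list, is a title gene that the study chose on these samples, so its call is not independent evidence. The microRNA machinery had medians of -0.01 in PC3M (0.05 with quantile normalization and 0.01 with normexp background correction) and 0.12 in PC3 (0.21 and 0.08 in these settings, adjusted p = 0.446). Within it AGO3, an Argonaute protein, was higher by 0.67 and TNRC6B, its partner in silencing, was lower by a mean difference of -0.58. Of the genes whose introns hold the miR-26 precursors, CTDSP2 was 2.61-fold lower in PC3M and 1.89-fold lower in PC3, CTDSP1 differed by -0.21 and 0.27, and CTDSPL was not well above background in PC3M and differed by 0.38 in PC3.

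Lists linked to p53 and to cell identity also moved alike in the 2 lines in part. The p53 target genes FAS, BTG2, TIGAR and SESN1, which act in cell death, growth arrest and metabolism, were higher in both lines, with mean differences of 1.58, 1.72, 1.68 and 1.24. Of the 20 genes, 9 were higher in both lines, 5 lower in both and 6 moved apart, and in PC3 10 were lower and 10 higher. The list's medians were 0.27 in PC3M (0.17 with normexp background correction) and 0.02 in PC3, the latter 0.09 with quantile normalization, 0.06 with normexp background correction, -0.06 when only probes well above background on all 4 arrays were kept and -0.01 with no filter on dim probes, and 4 genes were called higher when adjusted over the list alone. camera called it higher at an adjusted p of 0.0341 (0.728 with an estimated correlation and 0.156 with no filter on dim probes). Epithelial genes were lower in both lines in 14 of 22 measurable cases and higher in 3, with medians of -0.35 and -0.25, at percentiles 0.22 and 11.7 of matched random lists, and an adjusted p of 0.0035 (0.728 with an estimated correlation). With normexp background correction the medians were -0.20 and -0.23. The adherens junction gene CDH1 differed by -0.94 in PC3M and -1.17 in PC3, and the tight junction genes CLDN3 and TJP3 were lower in both, but CLDN1 was 3.21-fold higher in PC3. Mesenchymal genes had medians of 0.16 and 0.33 and were not called (adjusted p = 0.0695), but were called higher with quantile normalization (0.0436) and normexp background correction (0.0213). The median in PC3M was 0.02 when all 4 arrays had to be well above background, 0.05 with no filter and 0.09 with normexp background correction. SPARC, a matrix protein, was lower by a mean difference of -1.79. Adjusted over the list alone, 2 mesenchymal genes were called lower and 2 higher.

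Markers of other cell types were read in the same way. The stromal list had medians of 0.62 and 1.25 (adjusted p = 0.0013, and 0.728 with an estimated correlation), which were 0.02 and 0.14 with normexp background correction, where the call was absent (0.0945). Over its 8 genes measurable in PC3M and 7 in PC3, with dim signals at their bound, the medians were 0.37 and 0.82. Its members ACTA2 and FAP were higher in both lines, DCN was at least 1.28-fold and at least 1.54-fold higher from dim control arrays, and COL1A2 was 1.21-fold lower in PC3M and at least 3.39-fold higher in PC3. Leukocyte markers had medians of 0.23 and 0.22 (adjusted p = 0.0623), or 0.02 and 0.10 with normexp background correction, and were called higher with the mean of a gene's probes (0.0445), with CSF1R, a macrophage growth factor receptor, at least 9.80-fold higher in PC3M and 1.47-fold higher in PC3. Endothelial markers had medians of -0.46 and -0.19 (adjusted p = 0.217), the first of which was -0.03 with the mean of a gene's probes, -0.07 with no filter on dim probes and -0.12 with normexp background correction, and the junction gene ESAM was lower by a mean difference of -0.99. The androgen and luminal list had medians of -0.24 and 0.39 (adjusted p = 0.902), or -0.08 and 0.08 with normexp background correction, in which the prostate genes SLC45A3 and HOXB13 were lower by mean differences of -0.89 and -0.87. Of the neuroendocrine markers only ENO2, SYT1 and FOXA2 were tested. ENO2, a neuronal enolase, had a mean difference of -0.87, FOXA2 of -0.35, and SYT1, higher in PC3M and lower in PC3, of -0.27. The genes of hypoxia and glycolysis had medians of -0.20 and -0.13 (-0.09 and -0.01 with quantile normalization, -0.21 and -0.31 with the mean of a gene's probes). The glycolytic regulators PFKFB3 and PDK1 and the enzyme ALDOA were lower in both lines, and camera's adjusted p was 0.049 (0.728 with an estimated correlation, 0.486 with quantile normalization and 0.0700 with all 4 arrays required to be well above background). The stress-response list had medians of 0.12 in PC3M and -0.10 in PC3 (adjusted p = 0.902), which were 0.21 and 0.09 with quantile normalization. Its median over both lines was 0.03 and its mean -0.15, and the cystine transporter SLC7A11 and the glutathione-degrading CHAC1 were lower in both lines by mean differences of -1.58 and -1.67.

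The comparison within PC3M asked what the mimic did in the more metastatic line. FCGBP, a mucin-like secreted protein, STRADB and C9orf152 had the largest decreases, and VCX2, DHRS2 and ACTG2 the largest increases. Of 21 measurable cytokine genes 12 were higher and 9 lower, with CXCL8, the neutrophil attractant, 5.32-fold higher, and p53 targets such as BTG2 and TIGAR were 3.59-fold and 3.89-fold higher. SPARC was 4.91-fold lower and PLD1 3.23-fold lower. Of 34 measurable interferon-stimulated genes 21 were lower and 13 higher, with IFIT1 3.54-fold lower but CMPK2, IFI27 and RSAD2 1.93-fold, 1.81-fold and 1.64-fold higher.

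With 1 array per group no test was made. Of 23230 genes measurable in PC3M, 573 were more than 2-fold lower and 980 more than 2-fold higher after miR-26a, so that 63.1% of them were higher. With normexp background correction 178 were lower and 180 higher, or 50.3% higher. FCGBP went from 3.87 to 0.89, STRADB from 2.73 to -0.15 and C9orf152 from -0.07 to -2.76. VCX2 went from -3.34 to 4.72 and ACTG2 from -0.90 to 4.88. CXCL8 went from -1.97 to 0.44, BTG2 from -2.73 to -0.89 and SPARC from -0.12 to -2.42. The NF-kB and cytokine list had a median of 0.28, at percentile 99.98 of matched random lists, and the interferon list a median of -0.27, at percentile 0.85. With normexp background correction these medians were 0.04 and -0.10, at percentiles 93.5 and 26.2, and the cytokine median was 0.11 when only probes well above background on all 4 arrays were kept. Over the 21 measurable cytokine genes, with dim signals at their bound, it was 0.15. The DNA replication list (G1/S) had a median of 0.09, with the transcription factor E2F2 2.56-fold higher and the chromatin assembly subunit CHAF1A 2.20-fold lower. The mitotic list (G2/M) had a median of -0.07, which was 0.03 with quantile normalization, and its member CCNB1, the mitotic cyclin, was 1.89-fold lower.

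The comparison within PC3 asked the same of the parental line. Interferon-stimulated genes led the increases, with TRIM22 and XAF1, an antiviral ubiquitin ligase and a pro-apoptotic factor, ahead of DHRS2, and RSAD2, IFI27 and CMPK2 also far higher. Cytokine genes were higher as well, with CXCL8 4.89-fold and the NF-kB adaptor TRAF1 18.9-fold higher. Mitotic genes were lower throughout their list, with CCNB1 3.53-fold, the kinase PLK1 3.39-fold and the spindle protein DLGAP5 3.67-fold lower. Genes of cholesterol synthesis were lower, with MSMO1, a sterol oxidase, having the largest difference of its list. IL37, an anti-inflammatory cytokine, and VSIG1, an epithelial adhesion protein, had the largest decreases among coding genes.

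Of 23414 genes measurable in PC3, 853 were more than 2-fold lower and 1209 more than 2-fold higher, so that 58.6% of them were higher. With normexp background correction these counts were 358 and 379, or 51.4% higher. TRIM22 went from -4.27 to 2.60 and XAF1 from -3.33 to 2.95, which are 117-fold and 77.7-fold increases on single arrays. TRIM22's control level lay near -4.45, the lowest signal among probes well above background on that array, so the size of its fold is uncertain. RSAD2 was 28.7-fold, IFI27 26.0-fold and CMPK2 17.8-fold higher. IL37 went from 3.53 to 0.25, VSIG1 from 0.42 to -2.35 and the non-coding SH3TC2-DT from 0.47 to -2.25. In the interferon list 33 of 36 genes were higher, 27 of them by more than 2-fold, and the median was 1.84, above all matched random lists. Of 34 such genes measurable in both lines, 13 were higher in both, 3 lower in both and 18 moved apart. The NF-kB and cytokine list had a median of 1.30, with 23 of 26 genes higher. In the G2/M list 31 of 31 genes were lower, 21 by more than 2-fold, with a median of -1.09. In the G1/S list 31 of 32 were lower, with a median of -0.70, among them the replication genes MCM10 and FEN1, 2.57-fold and 2.24-fold lower, while E2F2 was 2.33-fold higher. In the cholesterol list 24 of 25 genes were lower, with a median of -0.83. The ribosomal protein list had a median of -0.47 (-0.21 with quantile normalization), and 42 of 42 genes were lower in PC3 and also in PC3M. The median in PC3M was -0.16, at percentile 55.4 of matched random lists, and with quantile normalization 30 genes were lower and 10 higher there.

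Over both lines, camera with its preset correlation called 12 of 21 lists, 8 lower and 4 higher, and 0 with an estimated correlation. An estimate from 1 residual degree of freedom gave no unadjusted p under 0.165, so the loss of a call with it says little about a list. The estimates themselves differed, at 1 for the ribosomal, G2/M, cholesterol and interferon lists, 0.875 for G1/S and -0.032 for the reported miR-26a targets. Where the estimate was 1, the lines' disagreement had the same sign in every gene of the list. The preset of 0.01 then treats genes that moved together as nearly independent, so its p-values for these lists may be too small. For the lists described within PC3, the adjusted p was 1.2e-05 for the ribosomal proteins, 1.8e-05 for the cytokines, 8.1e-05 for G2/M and 6.7e-04 for cholesterol synthesis. It was 0.0013 for the interferon genes, which camera called higher although their median in PC3M was negative, and 0.0251 for G1/S, which it called lower although their median in PC3M was positive. With an estimated correlation the adjusted p was 0.808 for the ribosomal, cytokine, G2/M, cholesterol and interferon lists and 0.823 for G1/S. The G1/S call was absent with quantile normalization (0.128). Adjusted over the list alone, 5 cytokine genes were called higher, and 0 genes of the other 5 lists. In the ribosomal list RPL22 and RPL3 had mean differences of -0.91 and -0.86.

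**Figure D2:**
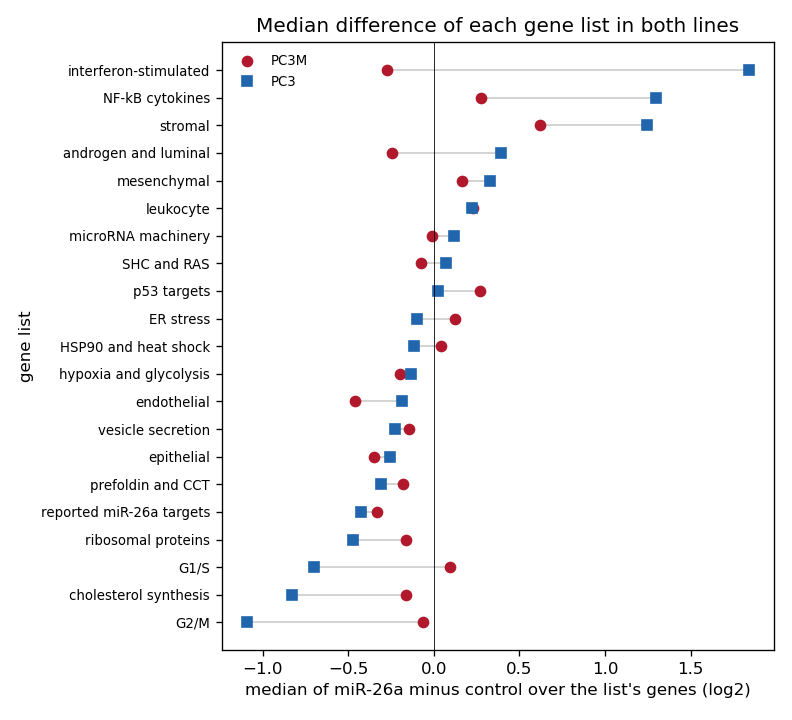
Median log2 difference between miR-26a and control over the genes of each of the 21 lists (horizontal axis) in PC3M (red circles) and PC3 (blue squares), with 1 array per group. Interferon-stimulated genes lay at -0.27 in PC3M and 1.84 in PC3, and G2/M genes at -0.07 in PC3M (0.03 with quantile normalization) and -1.09 in PC3.

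The next question was whether the unreplicated comparisons of the 2 lines gave the same genes. STRADB, POLR3G, DHRS2 and LCP1 stood out in both lines, whereas XAF1 was far higher in PC3 and not well above background in PC3M. TRIM22 was 117-fold higher in PC3, from a control level near the lowest signal well above background, and at least 3.59-fold higher in PC3M. The purine enzyme GMPR, the hair keratin KRT32, the lymphocyte adaptor HSH2D, the drug-conjugating enzyme UGT1A6 and the antiviral gene IFIT1 passed 2-fold in opposite directions. Across the 24178 genes, which are not independent replicates, the differences of the 2 lines correlated with a Pearson r of 0.431 and a Spearman coefficient of 0.430. The lines shared no control array. Among genes measurable in both lines, 83.3% of the 533 more than 2-fold lower in PC3M had the same sign in PC3, as did 82.1% of the 906 more than 2-fold higher. Starting from PC3, these shares were 83.6% of 809 and 78.2% of 1073. Among 22466 genes measurable in both lines, 180 were more than 2-fold lower in both, where independent lists would share 19.2, and 293 were more than 2-fold higher in both, where independent lists would share 43.3. In opposite directions, 34 genes passed 2-fold. With normexp background correction these counts were 66, 43 and 6.

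**Figure D3:**
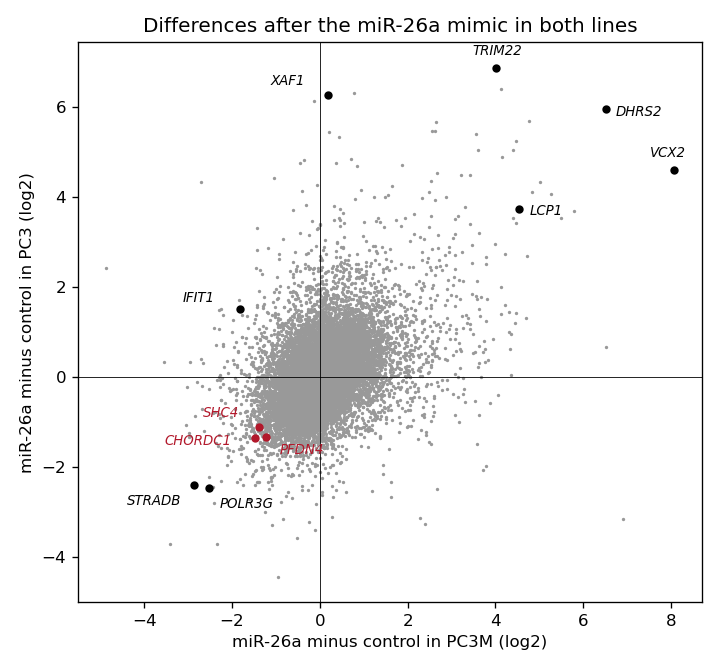
Log2 difference between miR-26a and control in PC3M (horizontal axis) against that in PC3 (vertical axis) for 24178 genes (grey points, as measured, dim probes included), with the title genes in red and other named genes in black. The title genes lay at -1.10 or lower in both lines, DHRS2 at 6.51 and 5.96, and IFIT1 on opposite sides of 0 at -1.82 and 1.52.

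The comparison of PC3M with PC3 over both treatments asked how far the lines themselves differ, as the background to their responses. PC3M had far more UCHL1, a neuronal deubiquitinase, more of the neuropeptide galanin (GAL) and more of the cancer-testis genes MAGEA6, MAGEA12 and MAGEA2B. PC3 had more INHBB and INHBA, the beta subunits of activins, more of the complement component C3 and more IL6, the iron-binding LCN2 and the leukocyte integrin ITGB2.

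limma called 7551 genes (31.2% of those tested), of which 3462 were lower and 4089 higher in PC3M. Of these, 2976 lower and 3100 higher genes differed by more than 2-fold, and 11434 genes had an unadjusted p under 0.05. UCHL1 had a mean level of 8.99 in PC3M and was not well above background in PC3, a difference of at least 11062-fold (adjusted p = 0.0031). GAL was at least 2829-fold higher, GALNT14, which starts O-glycosylation, at least 786-fold and the insulin-receptor adaptor GRB14 at least 362-fold higher in PC3M. The secreted peptide gene UTS2B was 417-fold higher (adjusted p = 0.0038). MAGEA6 had mean levels of 7.35 in PC3M and -4.67 in PC3 (adjusted p = 0.0048), where it was dim on the control array. MAGEA12 and MAGEA2B, dim on the same array, had mean levels of 5.01 and 6.14 in PC3M and -5.05 and -4.50 in PC3. INHBB was at least 393-fold, IL6 at least 384-fold and LCN2 at least 217-fold lower in PC3M, each dim on both PC3M arrays. By limma their adjusted p was 0.0031, 0.0075 and 0.0031. For these genes and for UCHL1, limma took the dim signals as measured, so its p-values do not test the bounded folds. C3 had mean levels of -2.44 in PC3M and 5.94 in PC3, a 332-fold difference. INHBA, the metalloprotease ADAM8 and ITGB2 were 199-fold, 194-fold and 184-fold lower in PC3M.

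By list, camera called interferon genes (adjusted p = 7.9e-11), cytokines (6.2e-10), mesenchymal genes (5.0e-05) and stress-response genes (8.5e-05) lower in PC3M. It called G1/S (3.8e-05), HSP90 (8.5e-05), cholesterol (9.4e-04), ribosomal (9.4e-04), prefoldin (0.0171) and G2/M genes (0.0267) higher. None of these 10 calls held with an estimated correlation (adjusted p = 0.759 for each), which had little power with 1 residual degree of freedom. The preset p-values of the interferon, cholesterol, ribosomal and G2/M lists may be too small here too, since their estimated correlation was 1. The prefoldin, G2/M and ribosomal calls were also absent with quantile normalization (0.154, 0.126 and 0.154), and hypoxia genes were called lower with quantile normalization (0.0200) and with all 4 arrays required to be well above background (0.0259). Of the interferon genes 21 of 36 were called lower over all genes tested and 31 when adjusted over the list alone, and of the cytokines 19 of 26 and 23. The median of all genes was 0.135 higher in PC3M, against 0.034 with normexp background correction, so that small differences between the lines depend on the scaling. With no filter on dim probes limma called 0 genes lower and 0 higher between the lines, with 12142 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.105.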

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

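In this part the test of the lower interferon median in PC3M was chosen only after its result was seen. The differences between the lines listed here were not themselves tested, since each line has 1 array per treatment. They were singled out because the arrays of one line moved one way and those of the other line the opposite way.

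In opposite directions in PC3M and PC3, 34 genes passed 2-fold, and 6 did with normexp background correction. Of those in the main analysis well above background on every array, the 5 furthest apart, as the difference in PC3M minus that in PC3, were GMPR at -3.74, KRT32 at 3.70, HSH2D at -3.54, UGT1A6 at -3.51 and IFIT1 at -3.34. GMPR and UGT1A6, enzymes of purine and drug metabolism, and HSH2D and IFIT1, genes of immune signalling and of the interferon response, were lower after miR-26a in PC3M and higher in PC3. KRT32, a hair keratin, was higher in PC3M and lower in PC3. As lists, the G1/S genes had a median that was 0.79 higher in PC3M than in PC3, and the interferon-stimulated genes one that differed by -2.11, although 13 of the 34 interferon genes measurable in both lines were higher in both.

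The interferon pattern was weighed against technical explanations. The list's median was -0.27 in PC3M and 1.84 in PC3. If the scaling of the arrays had made the difference, the medians would share a sign or lie within 1 of each other under at least 1 of the 4 scalings, but they kept opposite signs, and the smallest distance between them was 1.80. That argues against scaling as the cause of the distance between the lines. For the lower median in PC3M alone scaling stays open, since with normexp background correction it was -0.10, at percentile 26.2 of matched random lists. An effect of 1 array or culture that stands apart from its group cannot be told apart from an effect of the line, since there was 1 array per line and treatment. A difference in how the 2 lines respond to this mimic may also be the source, and the design gives no further array to test it. The control cells were also transfected with a microRNA, so a response equal under both treatments would not appear in the difference.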

How the results depend on the processing

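The word search in probe sequences was chosen only after the data were seen, and the other alternatives were planned. With the authors' value table, which repeats the main scaling, the reported counts and named genes kept their side, and 7541 of the 7551 line calls were shared. Among the named genes' values under the alternatives, 1007 kept direction and side, 16 lost a call, 2 gained one and 8 changed sign. The lost calls were line differences with no filter, and those gained were DHRS2's. Among values for the lists, 451 held, 33 lost a call, 8 gained one and 50 untested values moved.

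With normexp background correction, which compresses dim signals, PC3M had 178 genes past 2-fold lower and 180 higher, and PC3 358 lower and 379 higher. In both lines 66 were lower and 43 higher, and 6 went in opposite directions. The shares with the same sign were 90.3% of genes lower in PC3M, 88.4% of those higher in PC3M and 87.3% of those lower in PC3. With probes well above background on all 4 arrays, which tests fewer genes, 625 were past 2-fold higher in PC3M, 796 in PC3 and 189 in both. A 1.5-fold threshold gave 2292 lower and 2490 higher in PC3M and 3121 and 3059 in PC3. With no filter the lines' differences had a Pearson r of 0.227 and a Spearman coefficient of 0.290 across genes, and limma called 0 genes lower and 0 higher in PC3M against PC3, with 12142 at an unadjusted p under 0.05. The cause was not tested.

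limma called 1 gene higher over both lines, DHRS2, both with all 4 arrays required and with a trended, robust prior. In the other alternatives it called 0, with 481 genes at an unadjusted p under 0.05 without a block and 3891 to 4991 otherwise. Without a block 2426 genes were higher in PC3M than in PC3. Of the 7551 line calls, 6754 were also called with quantile normalization, 5855 with normexp and 4781 without a block. With an estimated correlation, which had little power at 1 residual degree of freedom, camera called 0 lists for miR-26a and 0 for the lines.

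The mean difference changed sign for HSH2D (0.0096 with quantile normalization, 0.25 with normexp, 0.15 with the mean of probes), IFIT1 (0.038 with quantile normalization), CTDSP1 (-0.016 with the mean of probes), TRPM8 (-0.00062 with normexp) and SYT1 (0.11 with normexp, 0.20 with the mean of probes). In each of these genes the lines' differences had opposite signs.

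Not run were the search of 3' UTRs and of the shortest UTR (no sequences), a slide or scan term (1 slide, 1 scan) and a test with 1 line left out, which leaves the single-line results. For dim probes signal over background limits folds to bounds.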

Other observations

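In this part the test of base composition, the search of probe sequences and the gene families were chosen only after results were seen, and the prediction for the seed match was written before its result.

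Among 14442 mRNA genes, 94 had the match to the miR-26a seed, TACTTGA, in a probe sequence. Their median log2 difference was -0.24 in PC3M, against -0.07 for the other genes, and -0.25 in PC3, against -0.06. By mean difference TACTTGA stood at percentile 0.0915 of 13115 words in PC3M and 0.343 in PC3, under the bound of 1% set for an effect through the seed match, although it lay at 1.08 in PC3 with normexp background correction. Divided by the standard error it ranked 2 in PC3M and 3 in PC3, and over the alternatives between 1 and 3 in PC3M and between 2 and 17 in PC3. The related match ACTTGAA, in 143 genes, ranked 1 and 2, and the match to the passenger strand, AGAATAG, ranked 9611 and 3722. TACTTGA was the lowest of 375 words with the same bases (percentile 0.267). That place cannot decide on base composition, since over both lines TACTTGA already ranked 5 among all words by mean difference. The words with the same bases had a median difference of 0.0038 over both lines, against -0.278 for TACTTGA. They were thus not lower as a group, which argues against base composition alone. At the other end of the ranking, words with no link to the seed reached sizes as large, TGCAATA at 4.89 standard errors in PC3M against -4.59 for TACTTGA, and GACCCCT at 4.16 in PC3 against -3.69. The size alone could thus have another source. The place of the word among the lowest is consistent with the mimic lowering mRNAs through its seed match, a hypothesis that sequences of whole 3' UTRs would test better than probes of 60 bases.

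All 42 ribosomal protein genes tested were lower after miR-26a in both lines, but with quantile normalization 30 were lower and 10 higher in PC3M, and the medians went from -0.16 to -0.06 in PC3M and from -0.47 to -0.21 in PC3. A trend of the difference with brightness over all genes was weighed, since the median of the brightest 6045 genes was -0.13 in PC3M and -0.18 in PC3. Under quantile normalization, which brought those medians to -0.01 and -0.04, the list stood at percentile 14.6 of matched random lists in PC3M and at 1.45 in PC3. In PC3M the list's lower signal may thus be part of the trend. In PC3 the low percentile cannot decide whether the trend is the whole cause. The random lists drew genes independently, whereas the ribosomal genes moved together, and matching in bins leaves differences of brightness within a bin. With quantile normalization the list's median in PC3, -0.21, was still below the -0.04 of the brightest genes. The trend thus stays open in PC3 too, and no biological explanation was tested.

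Some gene families were also read against matched random lists. C2H2 zinc finger genes (479 tested) had medians of 0.22 in PC3M and 0.18 in PC3 (0.10 in each with normexp background correction), with 245 of 444 measurable genes higher in both lines and 86 lower in both. Protocadherins (31 tested) had medians of 0.59 and 0.79, which were 0.08 and 0.13 with normexp. Keratins (38 tested) had medians of -0.35 in both lines (-0.16 and -0.13 with normexp), with 22 of 37 measurable genes lower in both. Proteasome subunits (44 tested) had medians of -0.30 and -0.37 (-0.18 and -0.21 with quantile normalization), with 36 lower in both and 4 higher. Complex I genes (48 tested) had medians of -0.21 and -0.24, at percentiles 11.3 and 37.1, and of -0.05 and -0.07 with quantile normalization. Cancer-testis genes of the MAGE families (13 tested) had medians of 0.36 and 0.38 (0.17 and 0.08 with normexp), but only 6 of them were measurable in both lines.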
